A study of Mus musculus with 8 samples.

How the data were processed

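Kidney pairs from E14.5 mouse embryos were snap frozen, and polyA-selected libraries were sequenced as paired reads, per the labels' protocols. There were 4 control and 4 mutant libraries, assigned to groups and numbered by their titles. Per the submitters' processing notes, the tools were fastp 0.23.2, kallisto 0.46.0 and DESeq2 1.40.2, with genome build mm10; the role and settings of each are not given in the sources used here. The deposited table of log2 values, named as normalized, covers 21291 gene rows in 8 columns. Per the values, the deposited log2 numbers are log2 of an estimated count plus 1 with no correction for depth: 2 to the power of the value, minus 1, was whole within 1e-06 for 73.4% of all values and 67.8% of values above 0, and summed to different totals per library. The authors' second file gives a mean normalized count (a signal), a log2 fold change with its standard error, a test statistic (a score) and p-values for 644 genes, as deposited by the authors and named per the file headers. How those p-values were computed is not given in the sources used here beyond the tool names. The authors' table is named as a subset, and how its genes were chosen is not given either.

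The design, fixed before the data were examined, took the log2 values as depth-corrected. Since they are not, estimated counts were recovered and divided by median-of-ratios size factors, which ran from 0.361 in control 4 to 1.27 in control 2, and the same limma test was kept. Genes with a normalized count of at least 10 in at least 4 libraries were tested on log2(normalized count + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend), genotype as the single term, two-sided, with Benjamini-Hochberg adjustment over 14974 genes and a threshold of 0.05. Fold changes are on that log2(value + 1) scale, which understates the change of low genes. Normalized counts are given as mean ± SD. Total estimated counts ranged from 15515139 to 39548327, so values from control 4 carry the largest counting error.

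All 26 gene lists were written before the data were examined, and were tested with limma camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists with at least 3 measured members. Of these, 12 passed with the preset correlation, 1 with an estimated correlation (the sex-linked list) and 3 by fry (the sex-linked, FGF/ERK feedback and FGF lists). A list score is the mean over members of the log2 normalized count minus the gene's mean, compared by exact permutation of the 8 libraries. Mitochondrial genes are listed under their file names. Named genes are Etv4 and Etv5, the 10 highest and 10 lowest fold changes among genes past the threshold whose groups did not overlap (leaving out unnamed gene models, Xist and Y-linked genes), and from each list up to 4 members past the threshold, or the 2 with the smallest p. A few genes that the rule names are not reported here. Other genes were picked out after their values were seen: Lars2, Kdm5c, ENSMUSG00000091478, and those marked so where they are named. Gene positions come from GENCODE M21 on GRCm38, the same assembly as mm10, and 95.5% of gene rows had a position. In the deposited log2 table, 2035 gene rows are identical to another row, none of them a named gene.

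The steps were tested on simulated data: negative binomial counts for the real genes, library sizes and spreads, with 200 genes changed. For the comparison of 4 mutant with 4 control libraries, over 15038 simulated genes tested, 72% of genes changed by 1 log2 unit and 90% of those changed by 2 were recovered, 4.55% of calls fell on unchanged genes, and 0 of 20 unmoved lists passed. Genes were drawn independently, with no correlation within lists and no deviations shared within a library. The simulation therefore does not show how often correlated real lists would pass with the preset correlation. Spearman correlations across genes between libraries ran from 0.963 to 0.994 within groups and from 0.962 to 0.991 between them; genes are not independent replicates. No libraries were identical, and none was left out of the main comparison. The alternatives covered filters, pseudocount, scaling, trend, weights, blocks, thresholds and each library left out in turn. Alternatives chosen after seeing the data were no depth correction, limma voom with and without library weights, both libraries named 816 left out, a tubule and podocyte covariate, voom without control 4, and counting genes outside X and Y. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.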

Results

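Polyadenylated RNA was sequenced from kidney pairs of E14.5 mouse embryos, with 4 control and 4 mutant libraries. Every embryo carried Six2-GFPcre, a transgene that drives Cre recombinase in nephron progenitors, the cells that form the nephron, and a homozygous floxed Etv5 allele. By the labels the genotypes differed at Etv4, which was heterozygous null in controls and homozygous null in mutants. Etv4 and Etv5 encode related ETS-family transcription factors that act downstream of FGF and GDNF-RET signalling. The question stated by the series is what losing both factors from nephron progenitors and their descendants does to kidney gene expression. As labelled, the groups differ only at Etv4, so their comparison does not isolate the loss of both factors. The labels also do not limit the Etv4 null allele to nephron progenitors. Total estimated counts were 35070907, 39548327, 34114519 and 15515139 in controls 1 to 4, and 38824018, 38524908, 35409848 and 35308934 in mutants 1 to 4. Control 4 was the shallowest library, and 18.4% of its counts came from Lars2, which encodes a mitochondrial leucyl-tRNA synthetase, against 0.138% to 0.476% in the other 7 libraries. The labels describe controls as littermates but do not say which embryos shared a litter, and each library is a separate kidney pair. The limma p-values below set the genotype difference against the spread within groups. They treat the 8 samples as independent, with no term for litter or sex.

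Etv4 (ENSMUSG00000017724, chromosome 11, 101769742 to 101785371, minus strand, GRCm38) fell in the mutants, from 2686 ± 250.4 normalized counts in controls to 239 ± 59.8 in mutants (mean ± SD, n = 4 each). Its log2 fold change was −3.51 (SE 0.18, limma adjusted p = 2.6e-05), it was lower in 4 of 4 mutant libraries, and it passed the threshold in 27 of 28 other fits; the remaining one, with Ddx3y as a covariate, called 0 genes and was set aside because that level follows genotype. Etv5 (ENSMUSG00000013089, chromosome 16, 22381309 to 22439719, minus strand) had 3614 ± 491 normalized counts in controls and 2120 ± 511 in mutants (n = 4 each). Its log2 fold change of −0.79 (SE 0.17) did not pass the limma threshold (adjusted p = 0.106), although every mutant library lay below every control library; it passed in 5 of 27 other fits, with adjusted p from 0.00918 to 0.648. The floxed Etv5 alleles and Cre are labelled as present in both groups. The labels were not tested against reads over the floxed exons, so whether the lower Etv5 values reflect deletion in mutants alone is left open.

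**Figure D1:**
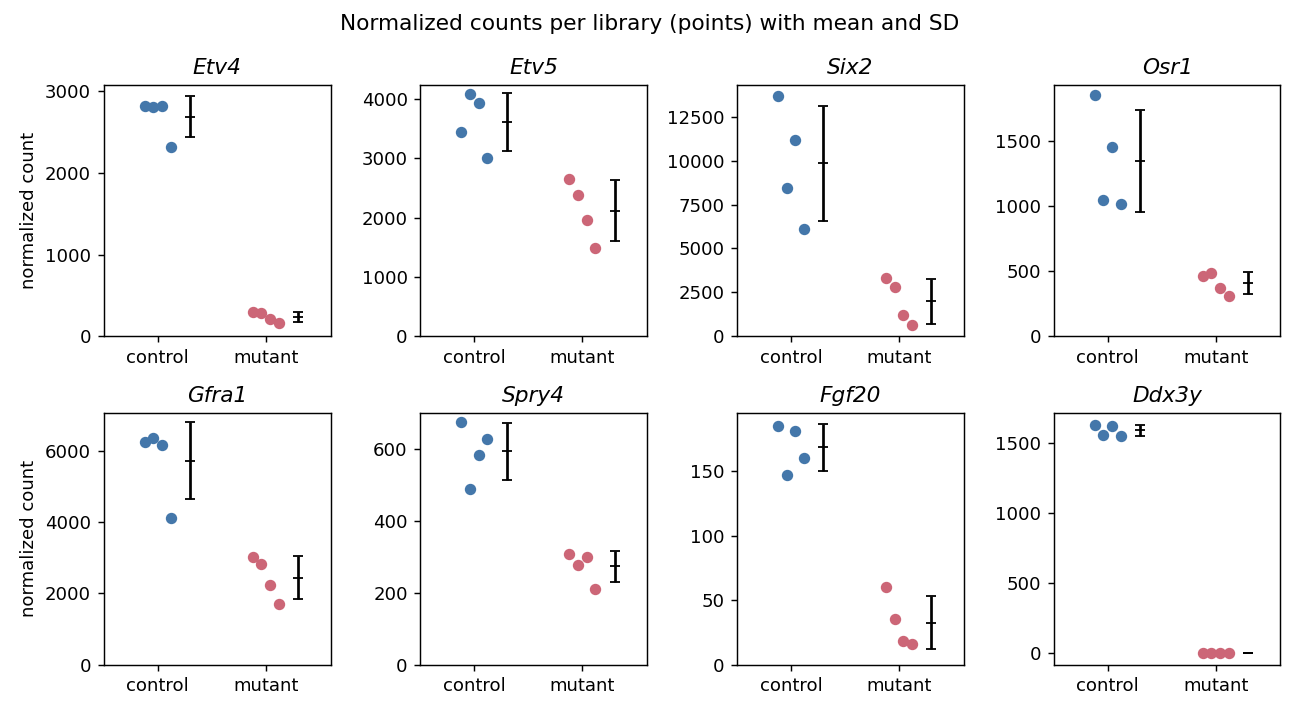
Normalized counts (vertical axis, estimated count divided by size factor) of 8 genes in the 4 control and 4 mutant libraries; points are libraries, and the bar beside them is the mean with its SD. Etv4 averaged 2686 in controls and 239 in mutants, and Ddx3y was 0 in every mutant.

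Transcripts of several other genes fell in mutant kidneys together with Etv4. Among the 10 lowest fold changes were Ocm, encoding the calcium-binding protein oncomodulin (log2 fold change −4.14, SE 0.60), Tafa4 (−3.20, SE 0.42), Dync1i1, a dynein intermediate chain (−3.19, SE 0.49), Crym (−2.87, SE 0.39), Colq (−2.86, SE 0.36), Defb36 (−2.61, SE 0.36), Fgf20 (−2.53, SE 0.40), Moxd1 (−1.87, SE 0.14) and Nell1 (−1.83, SE 0.19). The highest fold changes were smaller, at 1.89 for Frem3 (SE 0.30), 1.19 for Svopl (SE 0.15), 1.09 for Stac2 (SE 0.17), 0.84 for Kdm6a (SE 0.10), 0.81 for Syk (SE 0.12) and 0.81 for Scube3 (SE 0.13). Zswim6 (0.62, SE 0.10), Ehd2 (0.54, SE 0.08), Rai14 (0.52, SE 0.09) and Eif2s3x (0.52, SE 0.08) completed the 10 highest. All of these genes passed the limma threshold, with adjusted p between 2.6e-05 for Etv4 and 0.0457 for Rai14, and their mutant and control libraries did not overlap. Bmp7, a growth factor of the cap mesenchyme and ureteric bud that was picked out after its values were seen, also fell (−0.83, SE 0.13, limma adjusted p = 0.0329). Among fits that leave out 1 library it passed only without control 4, with adjusted p from 0.0542 to 0.148 when any other single library was left out. Of 14974 genes tested, 12 were higher and 33 lower in mutants at an adjusted p below 0.05, and 1804 had an unadjusted p below 0.05. Outside the X and Y chromosomes, 9 genes were higher and 28 lower among 14459 tested. Groups did not overlap for 8.60% of genes, where 2.86% would be by chance. Etv4 and Moxd1 passed in each of the 8 fits that leave out 1 library, while the other 18 of the 20 highest and lowest genes no longer passed without control 3 (adjusted p from 0.057 to 0.195). The number of genes past the threshold rested on single libraries: it was 10, 2 and 161 without control 1, 3 or 4, and 13, 19, 9 and 22 without mutant 1, 2, 3 or 4. It was 45 without control 2, and 10, 27, 2 and 42 of the original 45 genes still passed without controls 1 to 4, and 13, 17, 9 and 22 without mutants 1 to 4. With a control left out, Y-linked genes such as Ddx3y also fall below the filter of 4 libraries.

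The nephron progenitor list was lower in mutants by limma camera with a preset correlation (adjusted p = 6.4e-11), and had an adjusted p = 0.273 with an estimated correlation. Of the 20 genes on this list, 17 had negative fold changes, and 3 fell over all genes tested: Osr1, a transcription factor of the early kidney lineage (log2 fold change −1.69, SE 0.21, adjusted p = 0.0152), Crym (−2.87, SE 0.39, adjusted p = 0.0185) and the X-linked Capn6 (−0.95, SE 0.10, adjusted p = 0.0056). Osr1 no longer passed without control 3 (adjusted p = 0.106), mutant 1 (0.0525) or mutant 3 (0.0594), Crym without controls 1 or 3 or mutants 3 or 4 (0.0594 to 0.112), and Capn6 without control 3 (0.0557). Adjusted over the list alone, 13 were lower and 0 higher. Six2, the transcription factor that keeps nephron progenitors undifferentiated, averaged 9859 ± 3290.4 normalized counts in controls and 1971 ± 1281 in mutants (n = 4 each). Its log2 fold change of −2.55 (SE 0.49) missed the limma threshold (adjusted p = 0.0774, passing in 9 of 27 other fits with a range of 0.000769 to 0.272), as did those of Meox1 (−1.31, adjusted p = 0.0748), Eya1 (−1.23, adjusted p = 0.27), Gdnf (−0.93, adjusted p = 0.24) and Cited1 (−0.93, adjusted p = 0.104). Without control 4, Six2 (adjusted p = 0.0407) and Meox1 (0.0141) passed. These 5 genes were picked out after their values were seen. The list's mean centred log2 score differed by −0.79 between mutants and controls, against SDs of 0.27 in controls and 0.25 in mutants, with an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 can give, and 0.124 after adjustment over the 26 lists. The difference was −0.67 among controls 1 and 2 and mutants 1 and 2, which share a number in their library names, and −0.73 between control 4 and mutant 4, which share another. Ddx3y, Uty, Eif2s3y and Kdm5d, which are Y-linked, were present in every control and absent or near 0 in every mutant, so the genotype and the sex of the embryos cannot be told apart for this or any other list.

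**Figure D2:**
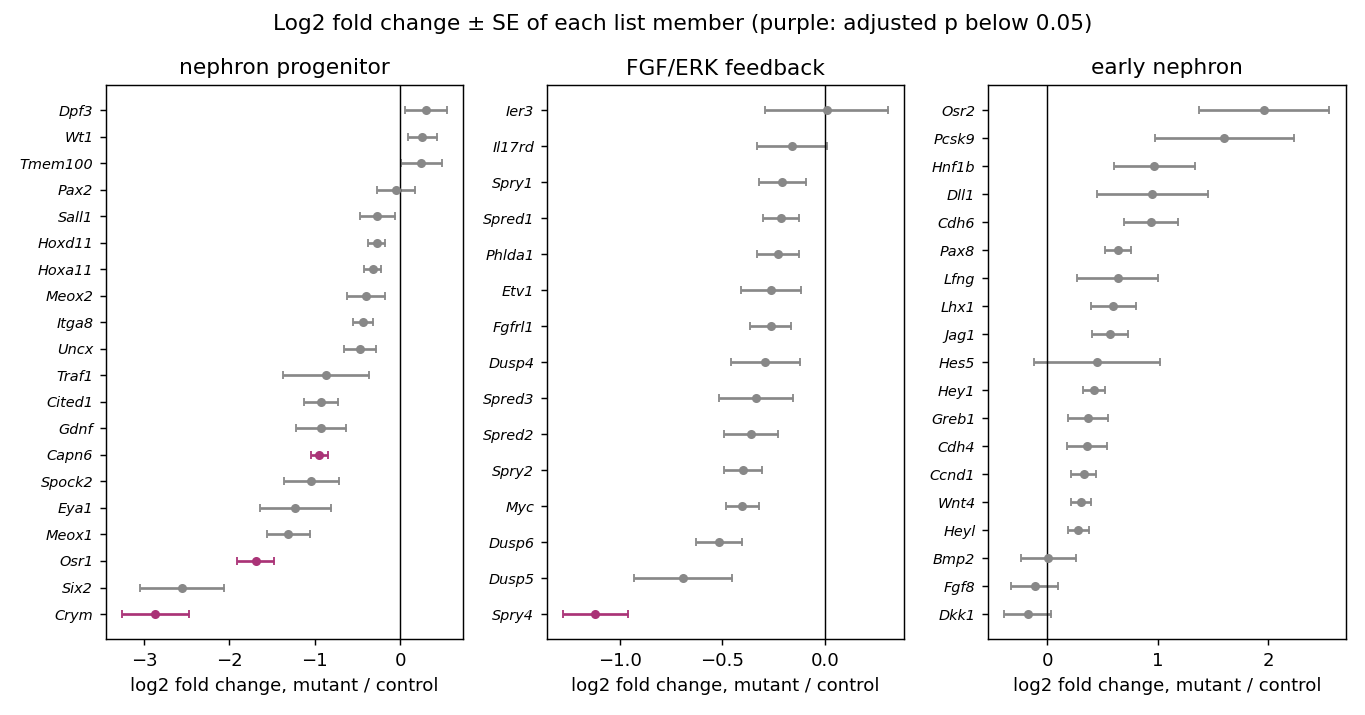
Log2 fold change of mutant over control (horizontal axis) for each measured member of 3 gene lists; points are limma estimates from 4 against 4 libraries, bars are SE, and purple marks an adjusted p below 0.05. In the nephron progenitor list 17 of 20 members are negative, in the FGF/ERK feedback list 14 of 15 are negative, and in the early nephron list 17 of 19 are positive.

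The list of FGF/ERK feedback targets was lower by camera (adjusted p = 2.9e-09), and had an adjusted p = 0.268 with an estimated correlation. Of 15 measured members 14 had negative fold changes, Spry4, an inhibitor of receptor tyrosine kinase signalling, fell (log2 fold change −1.12, SE 0.16, limma adjusted p = 0.0219, but 0.0562 to 0.126 without controls 1 or 3 or mutants 1, 2 or 3), and 7 were lower adjusted over the list alone. Dusp6, a phosphatase that inactivates ERK (−0.52, SE 0.11, adjusted p = 0.101), and Spry2 (−0.40, SE 0.09, adjusted p = 0.117) did not pass over all genes, and both were picked out after their values were seen. The list's median of −0.29 became 0.18 on the deposited values without depth correction, where the median of all genes was 0.48, and Spry2 then stood at 0.070. The score difference was −0.30 among controls 1 and 2 and mutants 1 and 2, and −0.40 between control 4 and mutant 4. Among 14 FGF ligands and receptors, Fgf20, a ligand made by nephron progenitors, fell (−2.53, SE 0.40, adjusted p = 0.0386, but 0.0769 to 0.168 without controls 1, 2 or 3 or mutants 2, 3 or 4), and 3 were lower adjusted over the list alone. That list did not pass by camera (adjusted p = 0.168) and was lower by fry (adjusted p = 0.0261), a test of whether the members move one way on balance.

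The early nephron list was higher in mutants by camera (adjusted p = 3.7e-08), and had an adjusted p = 0.273 with an estimated correlation, with no single member past the threshold over all genes. Of 19 measured members 17 had positive fold changes, and 10 were higher adjusted over the list alone. Pax8, a transcription factor of the forming nephron, had a log2 fold change of 0.64 (SE 0.12, limma adjusted p = 0.0688, or 0.00604 without control 4), and Hey1, a Notch target, one of 0.42 (SE 0.10, adjusted p = 0.11). Jag1 (0.57, adjusted p = 0.19), Osr2 (1.96, adjusted p = 0.22, or 0.0422 without control 4) and Wnt4 (0.31, adjusted p = 0.194) were on the same side, Jag1 and Osr2 having been picked out after their values were seen. The exact two-sided permutation p of the list's score was 0.0857, and the score difference was 0.60 among controls 1 and 2 and mutants 1 and 2 and 0.27 between control 4 and mutant 4. The Notch target list was higher by camera (adjusted p = 0.0376, then adjusted p = 0.363 with an estimated correlation), with 2 members higher and 1 lower adjusted over the list alone. It no longer passed without control 1 (adjusted p = 0.123), mutant 3 (0.0775) or mutant 4 (0.0527). The 2 higher genes, Hey1 and Heyl, are also on the early nephron list, so the 2 lists are not separate evidence. The lower gene was Hes1 (−0.41, SE 0.09, adjusted p = 0.101 over all genes), at 0.055 without depth correction. The BMP target list was higher by camera (adjusted p = 0.000653, then adjusted p = 0.363 with an estimated correlation), with 0 members past the threshold over all genes and 4 higher adjusted over the list alone, led by Bambi (0.50, SE 0.14) and Atoh8 (0.38, SE 0.11).

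The ureteric tip list was lower in mutants by camera (adjusted p = 7.8e-05), and had an adjusted p = 0.363 with an estimated correlation. Its score was 0.11 and −0.010 in mutants 1 and 2 and −0.41 and −0.87 in mutants 3 and 4, against 0.14 to 0.47 in controls. The difference was −0.34 among controls 1 and 2 and mutants 1 and 2, and −1.02 between control 4 and mutant 4. Gfra1, the GDNF co-receptor, fell from 5729 ± 1083 normalized counts in controls to 2449 ± 599 in mutants (n = 4 each, log2 fold change −1.24, SE 0.20, limma adjusted p = 0.0432). Among fits that leave out 1 library it passed only without control 4, with adjusted p from 0.0599 to 0.18 when any other was. Gfra1 was the single member of 10 past the threshold over all genes, and 6 were lower adjusted over the list alone. Wnt11, a tip-derived Wnt ligand (−0.84, SE 0.15, adjusted p = 0.058, or 0.0445 without control 4), Sox8 (−1.71, SE 0.44, adjusted p = 0.155) and Ret, the GDNF receptor (−0.77, SE 0.24, adjusted p = 0.237), were picked out after their values were seen and did not pass. The ureteric trunk list did not pass (adjusted p = 0.0783), but did without control 4 (0.00734), mutant 1 (0.0228) or mutant 2 (0.0405), and its leading members Gata2 (0.47, SE 0.13) and Tfcp2l1 (0.45, SE 0.14) had positive fold changes.

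Genes of differentiated nephron segments varied more between libraries than between genotypes. Hnf4a, a transcription factor of the proximal tubule, had 1547 normalized counts in control 4, 2262 in mutant 3 and 4877 in mutant 4, and between 1.84 and 282 in the other 5 libraries. Slc12a1, the loop of Henle cotransporter, had 332, 35.7 and 207 in those same 3 libraries and at most 14.2 elsewhere. These genes, with log2 fold changes of 3.21 (SE 1.73) and 0.50 (SE 2.15), were picked out after their values were seen. The number in the library name is shared by control 4 and mutant 4 and differs in mutant 3, and neither occurs among the other 5 libraries. The proximal tubule list, with 13 of 13 members positive, was higher by camera (adjusted p = 0.0035, then adjusted p = 0.663 with an estimated correlation), with 0 members past the threshold over all genes and 0 adjusted over the list alone. It no longer passed without control 1 (adjusted p = 0.106) or mutant 4 (0.184). Its leading members were Cubn (1.68, SE 0.84) and Lrp2 (1.27, SE 0.66), both endocytic receptors. The score difference of 1.74 was smaller than the SD of 2.26 in controls and 2.30 in mutants (exact two-sided permutation p = 0.286). The difference was 1.06 among controls 1 and 2 and mutants 1 and 2, and 1.37 between control 4 and mutant 4. Mutant 3 minus control 4 was −0.30. The podocyte list was higher by camera (adjusted p = 0.0041, then adjusted p = 0.44 with an estimated correlation), with 3 members higher adjusted over the list alone, among them Plce1 (0.59, SE 0.16). The loop and distal list did not pass (adjusted p = 0.551), with Irx3 at 0.70 (SE 0.27) and Emx1 at 1.29 (SE 0.51). The podocyte score differed by 0.12 among controls 1 and 2 and mutants 1 and 2, and by 0.49 between control 4 and mutant 4. The loop and distal score differed by −0.22 and −0.18 in the same comparisons.

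**Figure D3:**
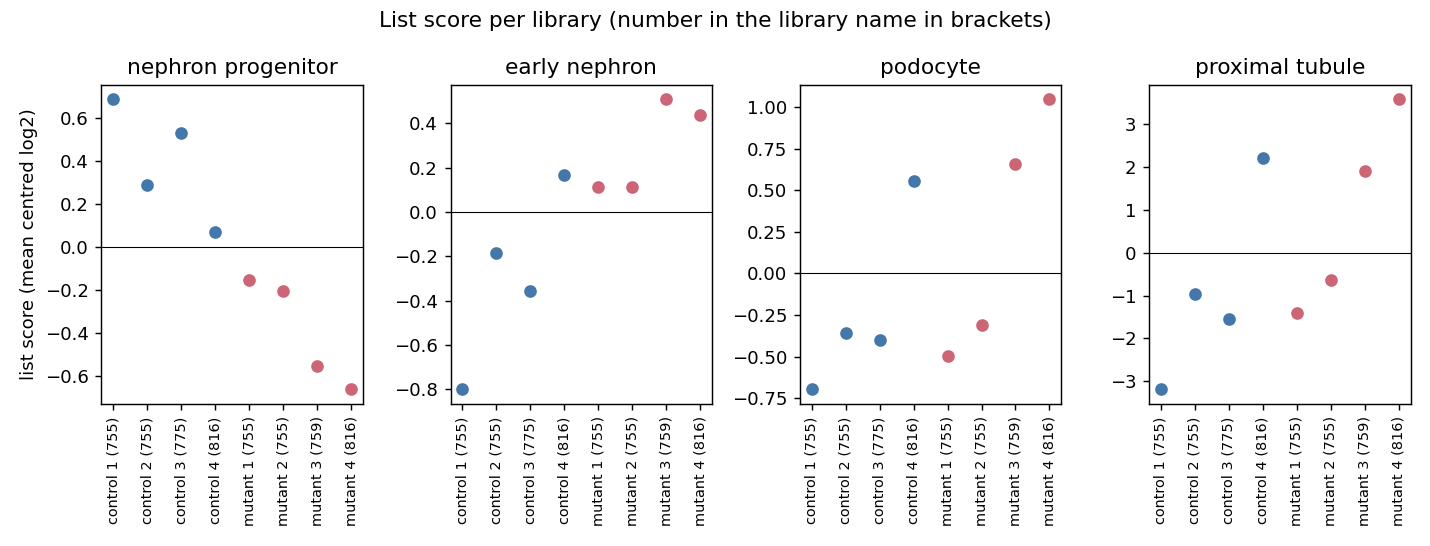
List score (vertical axis, mean centred log2 normalized count of the list's members) in each of the 8 libraries, controls in blue and mutants in red, with the number in the library name in brackets. The proximal tubule score is 2.22 in control 4, 1.91 in mutant 3 and 3.58 in mutant 4, and below 0 in the other 5 libraries.

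Endothelial and macrophage genes did not pass the threshold one by one. All 14 endothelial genes had positive fold changes, with 0 past the threshold over all genes and 3 higher adjusted over the list alone, among them the receptors Tie1 (0.55, SE 0.12) and Tek (0.42, SE 0.09). The list was higher by camera (adjusted p = 1.7e-07, then adjusted p = 0.294 with an estimated correlation), and its score differed by 0.34 among controls 1 and 2 and mutants 1 and 2 and by 0.21 between control 4 and mutant 4. The macrophage list was higher by camera (adjusted p = 6.3e-05, then adjusted p = 0.371 with an estimated correlation), with 4 of 13 members higher adjusted over the list alone, led by the complement gene C1qc (0.71, SE 0.16, adjusted p = 0.106, or 0.0283 without control 4) and Laptm5 (0.50, SE 0.12). The macrophage score differed by 0.51 among controls 1 and 2 and mutants 1 and 2, but by 0.040 between control 4 and mutant 4 and by 0.074 between control 4 and mutant 3 (exact two-sided permutation p over all 8 libraries = 0.114). With the tubule and podocyte score as a covariate, chosen after seeing the data, it differed by 0.23 (95% interval −0.086 to 0.54). Proliferation genes were lower by camera (adjusted p = 0.0285, then adjusted p = 0.706 with an estimated correlation), by a median of −0.086 that turned to 0.0055 among controls 1 and 2 and mutants 1 and 2 and to 0.38 without depth correction. That call was lost without control 1 (adjusted p = 0.118), control 2 (0.0675), mutant 3 (0.0832) or mutant 4 (0.706). Its leading members were Pcna (−0.18, SE 0.11) and Rrm2 (−0.17, SE 0.12), at 0.29 and 0.30 without depth correction. The stroma list did not pass (adjusted p = 0.371), and Ren1, the renin gene, had a log2 fold change of −2.38 (SE 0.44, adjusted p = 0.0744, or 0.0265 without control 4) and Fibin one of −0.70 (SE 0.18).

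The 4 Y-linked genes of the sex-linked list separated the groups completely, and the other 2 Y-linked genes tested, both unnamed gene models, did not. Ddx3y had 1768, 1973, 1743 and 561 counts in controls 1 to 4 and 0 in each mutant. Uty averaged 470.1 ± 54.5 normalized counts in controls and 0.613 ± 1.23 in mutants, Eif2s3y 825 ± 117 and 2.49 ± 3.46, and Kdm5d 748 ± 40.3 and 7.56 ± 5.60 (n = 4 each). All 4 measured members of the sex-linked list passed the limma threshold, Kdm5d no longer without control 3 (adjusted p = 0.0557), and the list passed with an estimated correlation (adjusted p = 0.0033). The X-linked Kdm6a and Eif2s3x, which escape X inactivation, rose, though neither passed without control 3 or mutants 1, 2 or 3 (adjusted p from 0.0562 to 0.132), nor Eif2s3x without control 1 or mutant 4. The X-linked gene model ENSMUSG00000098078 (Gm26992), picked out after its values were seen, had 0 counts in every control and between 18.3 and 57.1 normalized counts in the mutants. Xist was not analysed here.

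The authors' deposited table lists 644 genes, 383 higher and 261 lower in mutants, with adjusted p up to 0.0498. It is named as a subset, so its counts, and which chromosomes and lists it covers, may reflect how its genes were chosen. It gives Etv4 a log2 fold change of −3.55, Osr1 one of −1.83, Gfra1 −1.35, Six2 −2.49 and Etv5 −0.85. The mean normalized counts in the authors' deposited table matched means recomputed from the deposited log2 values within 1% for 99.7% of genes when control 4 was left out, and for 0.621% with all 8 libraries. Of 636 genes in the authors' deposited table with a position, 0 lay on X or Y. In the limma fit 620 of the 621 tested genes of that table had the same sign. Of the 37 limma calls outside X and Y, 36 were listed in it. Both comparisons rest largely on the same libraries, and that table holds genes already chosen at a low adjusted p. This agreement, and the directions of list members below, are therefore not independent support. The authors' deposited table holds 8 nephron progenitor genes, all lower, and 7 early nephron genes, all higher. It also lists 8 proximal tubule genes as higher. Its means match without control 4, whose proximal tubule score was 2.22, against −3.19, −0.96 and −1.55 in controls 1 to 3. With all 8 libraries, 0 members of the proximal tubule list passed over all genes in the limma fit.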

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

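All explanations in this part were tested after the result was seen. In groups of 4 libraries, 14 of 238 sets of values held a library far from the other 3 (its gap to the nearest, over the whole range, above the 95% critical value of Dixon's test), where chance gives about 1 in 20. Of these 6 were in control 4 and 3 in mutant 4. The total is close to that chance rate. Lars2, counted as a gene and again as a share of counts, and Kdm5c were picked out after their values were seen. The 3 in mutant 4 all concern mitochondrial transcripts. The tallies per library are therefore not separate tests and do not show an excess of outlying values.

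Lars2 took 18.4% of the counts of control 4 against 0.177% to 0.255% in the other controls, a log2 normalized count of 22.91 against 15.81 to 16.28. In the same library Etv4 stood at 11.17 against 11.45 to 11.46, Gfra1 at 12.01 against 12.59 to 12.64, Kdm5c at 11.71 against 12.49 to 12.56, and the erythroid list score at −1.25 against 0.21 to 0.50. In mutant 4, mitochondrial transcripts made up 3.67% of counts against 1.73% to 1.83% in the other mutants, with ATP6 at 17.43 against 16.48 to 16.55 and the mitochondrial list score at 0.86 against −0.25 to −0.087. Svopl was 8.34 in control 1 against 8.90 to 8.94, Uty was 8.61 in control 3 against 8.95 to 8.97 and 1.79 in mutant 1 against 0 in the other mutants. C1qc was 8.80 in mutant 3 against 8.53 to 8.57, and the FGF list score was −0.24 in mutant 1 against −0.10 to −0.087.

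Without control 4 the number of genes past the threshold rose from 45 to 161. Thinning control 1, 2 or 3 to the depth that control 4 has outside Lars2 gave 178, 196 and 173 genes in the 7-library fit, a median of 178, which argues against lower depth as the whole cause. More advanced tubule and podocyte expression in control 4 may contribute: with that score as a covariate 292 genes passed over all 8 libraries. But 12 of 100 random lists of 40 genes gave as many calls when used as a covariate (median 18), so this cannot be told apart from other differences that the same libraries share. RNA quality and the origin of the Lars2 counts were not tested.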

How the results depend on the processing

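The direction of the nephron progenitor list did not turn, and Etv4 passed, in 27 of 28 other fits, the Ddx3y covariate fit being set aside, but the count of genes over all 28 rested on the settings and on single libraries. In counts given as higher and lower, with those outside X and Y in brackets, 12 and 33 (9 and 28) became 8 and 22 (5 and 17) with no filter and 7 and 21 (5 and 15) for limma without trend. They became 333 and 415 (319 and 397) with limma library weights, where control 4 had a weight of 0.196, and 3 and 15 (2 and 11) in controls 1 and 2 against mutants 1 and 2 (2 against 2). By construction they were 44 and 78 (40 and 70) at a threshold of 0.1 and 0 and 8 (0 and 3) at 0.01. Leaving out each replicate gave 0 to 53 higher (0 to 48) and 2 to 108 lower (2 to 102), and 8 to 16 lists. The labels give no pairing. Deviations of same-numbered libraries correlated at 0.27, 0.098, −0.13 and 0.35. Controls 1, 2 and 4, but not 3, correlated best with their own number. The margin was small for control 1 (0.27 with mutant 1, 0.24 with mutant 2) and control 2 (0.098 with mutant 2, 0.068 with mutant 1). Control 4 and mutant 4 also share a library-name number, so these values do not show pairing by replicate number. The replicate block gave 45 and 88 (41 and 82). With the library-name number as a term there were 8 and 28 (6 and 23), and 19 of the 45 genes still passed. With Ddx3y as a covariate limma called 0 and 0 (0 and 0), with 1896 genes at an unadjusted p below 0.05. That fit is void because genotype accounts for 99.998% of the Ddx3y level. It turned the sign of 63 of 90 named genes, with log2 values up to 1042 in size, so its values per gene and list are not given.

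Chosen after seeing the data, no depth correction gave 62 and 18 (60 and 14), with a median over all genes of 0.48, so that 77.5% of calls were higher against 26.7%. Voom gave 20 and 49 (16 and 43), and with library weights 265 and 309 (253 and 293). Leaving out control 4 and mutant 4 gave 58 and 129 (51 and 119), the tubule and podocyte covariate 127 and 165 (120 and 154), and voom without control 4 gave 32 and 102 (28 and 97). Camera with an estimated correlation passed 1 list and fry 3, against 12. The cause of these differences was not tested except where stated.

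Genes that turned sign and lists whose camera direction turned were not past the threshold, except the proliferation list. Besides these, without depth correction the FGF/ERK feedback median turned to 0.18 and the proliferation median to 0.38, while their camera directions, which are relative to all genes, did not. In controls 1 and 2 against mutants 1 and 2 they were Myl1 0.26, Rrm2 0.052, Lars2 0.26, and list medians of 0.0055 for proliferation, 0.025 for stroma, 0.75 for muscle, 0.020 for glycolysis and hypoxia and −0.39 for adrenal and gonad. With the library-name number as a term they were Slc12a1 −1.07, Wnt targets 0.049, loop and distal −0.071 and adrenal and gonad −0.092. Without depth correction they were Tcf7 0.084, Hes1 0.055, Zmat3 0.049, Pcna 0.29, Rrm2 0.30, Ier2 0.049, Spry2 0.070, erythroid 0.79 and Wnt targets 0.57. With the tubule and podocyte covariate they were Slc12a1 −1.72, mitochondrial −0.19, loop and distal −0.35 and immediate early −0.097. The glycolysis and hypoxia list was −0.024 with quantile normalization, 0.036 with library weights, 0.015 by voom with library weights, −0.049 without control 4 and mutant 4 and −0.058 by voom without control 4. Adrenal and gonad was −0.15 with median centring, 0.030 with library weights, −0.10 by voom, 0.032 by voom with library weights, 0.087 without control 4 and mutant 4 and 0.11 by voom without control 4. Muscle was 0.68 with library weights, 0.65 by voom with library weights and 0.48 without control 4 and mutant 4, and Lars2 was 0.13 without both and 0.11 by voom without control 4. Over fits leaving out each replicate, ranges were −0.53 to 1.67 for Slc12a1, −2.26 to 0.11 for Lars2, −2.57 to 0.15 for Myl1, −0.21 to 0.36 for mitochondrial, −0.090 to 0.52 for loop and distal, −0.11 to 0.050 for immediate early, −0.24 to 0.14 for adrenal and gonad, −0.075 to 0.0038 for glycolysis and hypoxia, −0.044 to 0.42 for erythroid and −0.84 to 0.48 for muscle. A camera direction can turn while the median keeps its sign. Of the other gene values, 1965 kept direction and side, 170 came to pass and 238 no longer passed; for lists these were 639, 28 and 41. The edgeR and DESeq2 fits, planned only if whole counts could be recovered, were not run, since the recovered counts are estimates and many are not whole.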

Other observations

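Further lists gave values on neural, muscle, stress and metabolic genes. Des, which encodes desmin, had a log2 fold change of −1.17 (SE 0.20, limma adjusted p = 0.058, or 0.0265 without control 4) and was lower in 4 of 4 mutant libraries, but the muscle list did not pass (adjusted p = 0.544), its median being 0.17, its mean −0.14 and its test direction lower; without mutant 2 it passed (adjusted p = 0.000242), and Myl1 varied within groups (−1.26, adjusted p = 0.766). The neural list did not pass (adjusted p = 0.126, or 0.0412 without mutant 2), with Nefl at −1.17 (SE 0.54) and Stmn2 at −0.70 (SE 0.33). The adrenal and gonad list had 5 measured members, a median of −0.13, a mean of 0.31 and a lower test direction (adjusted p = 0.938), with Nr5a1 at 2.26 (SE 0.88) and Star at −0.57 (SE 0.30). For erythroid genes (adjusted p = 0.275) Gata1 was 1.79 (SE 1.02) and Epor 0.42 (SE 0.24).

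No member named in this paragraph passed over all genes in the limma test of the report. Jun was 0.46 (SE 0.08) and Ier2 −0.42 (SE 0.08), both with a limma adjusted p of 0.0688 (0.0436 and 0.0407 without control 4), in an immediate early list that did not pass (adjusted p = 0.861; median −0.010, mean 0.023, test direction higher). The hexokinase gene Hk2 was −0.81 (SE 0.19, adjusted p = 0.111, or 0.0288 without control 4) and the phosphofructokinase gene Pfkp 0.79 (SE 0.17) in a glycolysis and hypoxia list that did not pass (adjusted p = 0.755). In the p53 list (adjusted p = 0.515) Ccng1 was 0.28 (SE 0.08) and Zmat3 −0.42 (SE 0.14). In the Wnt target list (adjusted p = 0.515; median 0.099, mean −0.0040, test direction higher) Tcf7 was −0.39 (SE 0.10). The interferon list did not pass (adjusted p = 0.0708, or 0.0408, 0.032 and 0.0487 without control 4, mutant 2 or mutant 3), with Rsad2 at 0.32 (SE 0.16), nor did the mitochondrial list (adjusted p = 0.551, or 0.00245 without control 4), with ATP6 at 0.61 (SE 0.40) and ATP8 at 0.56 (SE 0.43).

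The tests from here on were all chosen or carried out after the results were seen. Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many as 45 genes past the threshold, and the highest other gave 1. For genes outside X and Y, only 1 of the 35 splits gave as many as 37, and the highest other gave 1. The real split was thus the highest of 35, a share of 2.86%, the smallest that 35 splits can give. That makes a random grouping of the libraries unlikely without excluding it. A difference that follows the genotype groups, such as sex, is not tested by these splits.

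A hypothesis for the lower nephron progenitor list is a smaller or less maintained progenitor pool in mutants. With the tubule and podocyte score as a covariate, the nephron progenitor score difference was −0.63 (95% interval −0.75 to −0.51), against −0.79 without it. A later stage of the mutant kidneys, as that covariate measures it, did not account for the whole difference. The covariate ran from −1.64 to 1.34 in controls and from −0.91 to 1.93 in mutants, so it followed genotype only in part. A later stage that it does not capture is left open. Control 4 had the lowest nephron progenitor score of the controls (0.071, against 0.69, 0.29 and 0.53 in controls 1 to 3). Leaving it out could only widen the difference, to −0.90. That library therefore narrowed the difference and did not produce it. Sex cannot be told apart from genotype, because Ddx3y expression matched genotype in 8 of 8 libraries, so it may account for part of any difference. Whether progenitor number or expression per cell differs was not tested.

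Genes near Etv4 had an unadjusted limma p below 0.001 more often than genes elsewhere. Leaving out Etv4, 8 of 286 tested genes within 10 Mb did (2.80%), against 0.887% on other autosomes. Among them Stac2 rose (1.09, SE 0.17) and Tob1 fell (−0.90, SE 0.15), though both calls were lost when any single mutant or control 3 was left out, Stac2 also without control 2 and Tob1 without control 1 (adjusted p from 0.0769 to 0.195). Meox1 (−1.31, SE 0.25), Med1 (−1.02, SE 0.18) and Rara (−0.48, SE 0.10) did not pass in the limma test of the report. They passed in 7, 10 and 6 of 27 other fits, without control 4 among them (0.0141, 0.0194 and 0.029), with adjusted p from 0.00191 to 0.626 for Meox1 and Med1 and from 0.00531 to 0.987 for Rara, and like Tob1 were picked out after their values were seen. A candidate explanation is a chromosome 11 haplotype carried along with the Etv4 null allele, since 2.10% of windows of as many genes on other autosomes held as many such genes; with a 20 Mb window the share was 5.00%. Leaving out members of the fixed lists took the 10 Mb window from 286 to 278 genes, and 7 genes with p below 0.001 remained. Few neighbours are on those lists, so other genes of the changed cell types were not covered. Effects of Etv4 on its neighbours were not tested, and overlapping windows are not independent, so this may be a chance cluster. In the authors' deposited comparison, named as a subset, 24 of 635 positioned genes other than Etv4 lie in that window. By the share of tested genes 13.1 would lie there. ENSMUSG00000091478, a processed pseudogene at chromosome 11, 100361716 to 100362126, had 452, 495 and 430 normalized counts in controls 1 to 3. It had 0 in control 4 and at most 1.67 in the mutants.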
